A study of Caenorhabditis elegans with 8 samples.

How the data were processed

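RNA was measured in 8 pools of whole Caenorhabditis elegans of the strain CL2006, which expresses the human amyloid beta peptide in body wall muscle. The worms were fed bacteria carrying an empty RNAi vector (4 libraries) or a cpr-6 RNAi construct (4 libraries), per the labels' protocols, over 2 generations at 20 °C, and were harvested at day 6 of adulthood with progeny removed by daily transfer. Libraries were made with CEL-Seq2, a method that sequences the 3′ ends of polyadenylated transcripts, per the labels' protocols. The series text states 4 biological repeats. Beyond that statement, nothing in the labels shows that libraries with different numbers came from separate cultures, and p-values measure the spread between these libraries.

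The authors deposited a table of raw counts for 46904 genes, with normalized counts, log2 fold changes, standard errors and p-values from their own comparison beside them. Per the submitters' processing notes, cutadapt 2.10, TopHat2 2.1.1, HTSeq 0.12.4 and DESeq2 1.30.1 were used with the genome build WBcel235. The role and settings of each tool, the annotation release, the use of strand and the use of molecular identifiers are not given in the sources used here. If reads were counted without collapsing identifiers, amplified copies would enter the counts, and without strand, overlapping genes on opposite strands share reads. In the deposited table the normalized counts equal the raw counts times 1 constant per library, so no batch correction is visible in them. The authors' p-values cover the 13217 genes with 24 or more counts summed over the libraries, and the 33687 other genes carry none. The deposited log2 fold changes were compared with 5 DESeq2 models. A model with treatment and a term separating replicates 1 and 2 from replicates 3 and 4 came within 0.001 for 13217 of 13217 genes. The other 4 models came that close for at most 19.0% of genes. No label states this term, although the headers of the normalized counts contain the word noBatch. What this division stands for is unknown, and it was not part of the design fixed here.

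Total counts per library ranged from 8184412 to 12506320, and 15591 to 16414 genes had at least 1 count. Counts were analysed with R 4.3.3 and edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood fit, two-sided test of treatment alone), which left 10932 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are given on the log2 scale with standard errors, and levels as CPM (counts scaled to a common library size) with the SD over 4 libraries. The 95% intervals across all genes came from limma 3.58.1 voom. The cpr-6 level was also tested with an exact two-sided permutation test.

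Gene lists were fixed from textbook knowledge before the data were examined, and 34 lists with 3 or more measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation, fry and an exact permutation of list means stood beside it. The size of a list's difference is the mean log2 fold change of its members in edgeR. List levels per library, used for exact tests and for differences within replicate numbers, are mean log2 CPM with a prior count of 2. The rule for named genes was also fixed beforehand. It took cpr-6, then up to 12 genes per direction among those past the test with a mean count of 10 or more and no overlap between groups, up to 4 members with the smallest p of each list described, and all members of the cathepsin B family, insulin/IGF signalling and transgene-linked lists as values. With fewer than 10 genes past the test, the 10 with the smallest p were given as values. Genes of the authors' deposited table that fall outside this rule were chosen after their values were seen.

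The gene test was tried on counts simulated from the real means and library sizes over 10756 genes. It recovered 30 of 67 genes changed 1.5-fold (44.8%), 55 of 67 changed 2-fold (82.1%) and 65 of 66 changed 4-fold (98.5%), with 15 false calls. All these genes were changed in the same simulated counts, which eases the adjusted threshold. The rates are therefore higher than would hold where few genes change. Camera called 0 of 34 unchanged lists in the simulated counts, where genes were drawn independently. Within groups, library pairs differed by more than counting noise (chi-square per degree of freedom 5.89 to 29.0), although amplified copies alone could raise this value. All 8 libraries were kept as the separate samples the labels name. Alternatives were other scalings, other filters, DESeq2 1.42.0, voom, the replicate number as a block, each library left out in turn and, chosen after seeing the data, the same leave-outs with the genes of all 8 libraries kept and the term separating replicates 1 and 2 from replicates 3 and 4. Gene positions come from the deposited table. Of its gene identifiers, 46817 were found in Ensembl release 115 of the same build, which gave exons and overlapping genes.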

Results

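The series asks how whole worms that express amyloid beta differ in transcript levels when cpr-6, a cathepsin B-like cysteine protease gene, is knocked down by RNAi. Empty vector libraries held 9489866, 9654550, 11400011 and 12506320 counts for replicates 1 to 4, and cpr-6 RNAi libraries held 10715162, 10013467, 10837163 and 8184412. The vitellogenin gene vit-5 took the most counts in every library except cpr-6 RNAi replicate 2, where the small heat shock gene sip-1 did. Genes of the mitochondrial genome took 0.805% to 1.156% of counts in 7 libraries and 2.144% in cpr-6 RNAi replicate 4. That library also lay apart from the others on the first principal component (40.7 against -19.7 to 5.16), which held 32.9% of the variance.

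cpr-6 transcripts fell strongly under cpr-6 RNAi. The gene (WBGene00000786; WBcel235 chromosome X, 6607203 to 6609045, plus strand) stood at 758 ± 22.5 CPM (SD, n = 4) in empty vector libraries and at 81.7 ± 14.7 CPM (SD, n = 4) in cpr-6 RNAi libraries, or 10.8% of the control level. All 4 cpr-6 RNAi libraries (79.5, 80.2, 65.6 and 101 CPM) lay below all 4 empty vector libraries (749, 731, 773 and 780 CPM). The annotation gives cpr-6 a single transcript of 8 exons, with a 5′ UTR at 6607207 to 6607251 in exon 1 and a 3′ UTR at 6608971 to 6609045 in exon 8. The log2 fold change was -3.22 ± 0.114 (SE), with an adjusted p of 2.00e-10 in edgeR's quasi-likelihood test. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows. Within replicates 1 and 2 the difference was -3.21, and within replicates 3 and 4 it was -3.25. Neighbouring genes on the X chromosome that could be tested did not pass edgeR's test, with log2 fold changes of 0.17 for ttr-6, -0.06 for hic-1, -0.06 for clec-266 and -0.02 for kqt-1.

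**Figure D1:**
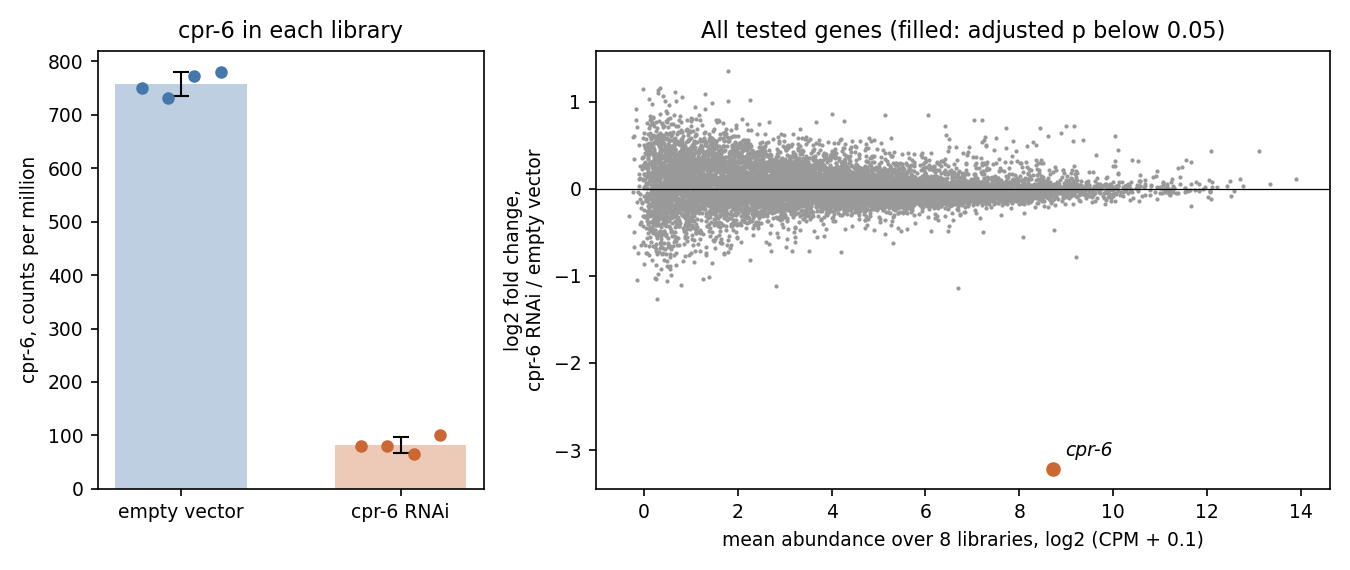
Left, cpr-6 in CPM for each library (points), with the group mean (bar) and SD (whisker, n = 4). Right, log2 fold change of cpr-6 RNAi over empty vector against mean abundance for the 10932 tested genes, where cpr-6 at -3.22 is the gene past adjusted p under 0.05.

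Across the rest of the transcriptome, no gene besides cpr-6 passed the test. Of 10932 genes, edgeR called 1, with 0 higher and 1 lower, and limma voom also called 1. DESeq2 called 5, and edgeR with no low-count filter called 28. Some of the 28 were also tested with the filter, such as swsn-3 and ugt-66 (edgeR adjusted p 0.728 and 0.820, and 0.00118 for both without it). Without the filter cpr-6 had an edgeR adjusted p of 8.29e-195 at a log2 fold change of -3.24. The filter therefore changed the estimated spread and not only the genes tested. In edgeR with the filter, the next smallest adjusted p was 0.539. Unadjusted p was under 0.05 for 421 genes, where 546.6 would be expected by chance. The groups did not overlap for 275 genes (2.52%), against 2.86% expected by chance. For 9689 genes (88.6%) the 95% interval of the fold change lay within 2-fold in either direction. The median half-width of that interval was 0.33 on the log2 scale, and, over 4 classes of genes of equal number by abundance, ran from 0.69 in the least abundant to 0.20 in the most abundant. Within replicates 1 and 2 alone edgeR called 99 genes, and within replicates 3 and 4 alone it called 1. A test of whether the treatment effect differed between these pairs of replicates called 0 genes (edgeR; 418 at unadjusted p under 0.05, smallest adjusted p 0.730).

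The 10 genes with the smallest p after cpr-6 did not pass edgeR's test and are given as values. F59C6.18 (chromosome I) stood at 1.86 ± 0.118 CPM (SD, n = 4) in empty vector and 4.83 ± 1.40 CPM in cpr-6 RNAi libraries, a log2 fold change of 1.36 ± 0.262 (SE) with an edgeR adjusted p of 0.539. The ubiquitin-conjugating enzyme gene ubc-1 stood at 103 ± 6.68 and 76.7 ± 5.08 CPM (log2 fold change -0.43 ± 0.0893, edgeR adjusted p 0.582). Y17G7B.20, which overlaps ash-2 on the other strand, had a log2 fold change of -0.47 ± 0.0978 (edgeR adjusted p 0.582), and swsn-3, which encodes a chromatin remodelling subunit of the SWI/SNF complex, one of -0.72 ± 0.158 (edgeR adjusted p 0.728). The myosin chaperone gene unc-45 had a log2 fold change of -0.39, K06A5.1 one of -0.46, atic-1 one of 0.58, Y48E1B.8 one of 1.01, the saposin-like gene spp-17 one of 0.58 and the glucuronosyltransferase gene ugt-66 one of 0.78. DESeq2 called ubc-1, Y17G7B.20, swsn-3 and F59C6.18 besides cpr-6.

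The authors' deposited table holds 7 genes at adjusted p under 0.05 and 15 under 0.1, 11 of them higher and 4 lower under cpr-6 RNAi, with 443 at unadjusted p under 0.05. In the authors' deposited table cpr-6 has a log2 fold change of -3.24, the cuticle collagen gene col-101 has 0.73 (adjusted p 0.00564), swsn-3 -0.74 (0.0205), F56D6.9 0.81 (0.0205), Y17G7B.20 -0.49 (0.0252), col-143 0.60 (0.0252) and F59C6.18 1.35 (0.0252). The authors' deposited table adds col-106, col-122, col-140, ubc-1, ugt-66, the glutamine synthetase gene gln-3, spp-17 and acp-6 under 0.1, which makes 5 collagens. edgeR with treatment alone gave adjusted p of 0.539 to 0.997 for the 14 genes besides cpr-6, although 14 of the 15 genes had an unadjusted p under 0.05. edgeR with a term separating replicates 1 and 2 from 3 and 4, chosen after seeing the data, also called 1 gene, cpr-6, with 547 at unadjusted p under 0.05 and adjusted p of 0.325 for F59C6.18, ubc-1, Y17G7B.20 and swsn-3. All 14 differed in the same direction within replicates 1 and 2 and within replicates 3 and 4. These genes were picked by small p in the same libraries, and the deposited values match a model with a term for this division. Their agreement is therefore largely fixed by the choice and adds no independent evidence. In 5 of the 5 collagens the lowest libraries were empty vector replicates 1 and 2, and the highest was cpr-6 RNAi replicate 4. Without cpr-6 RNAi replicate 4 the collagens' folds were 1.28 to 1.39. Reads of col-101 and col-122 may be shared with drl-1 and lron-14, which overlap them on the other strand.

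**Figure D2:**
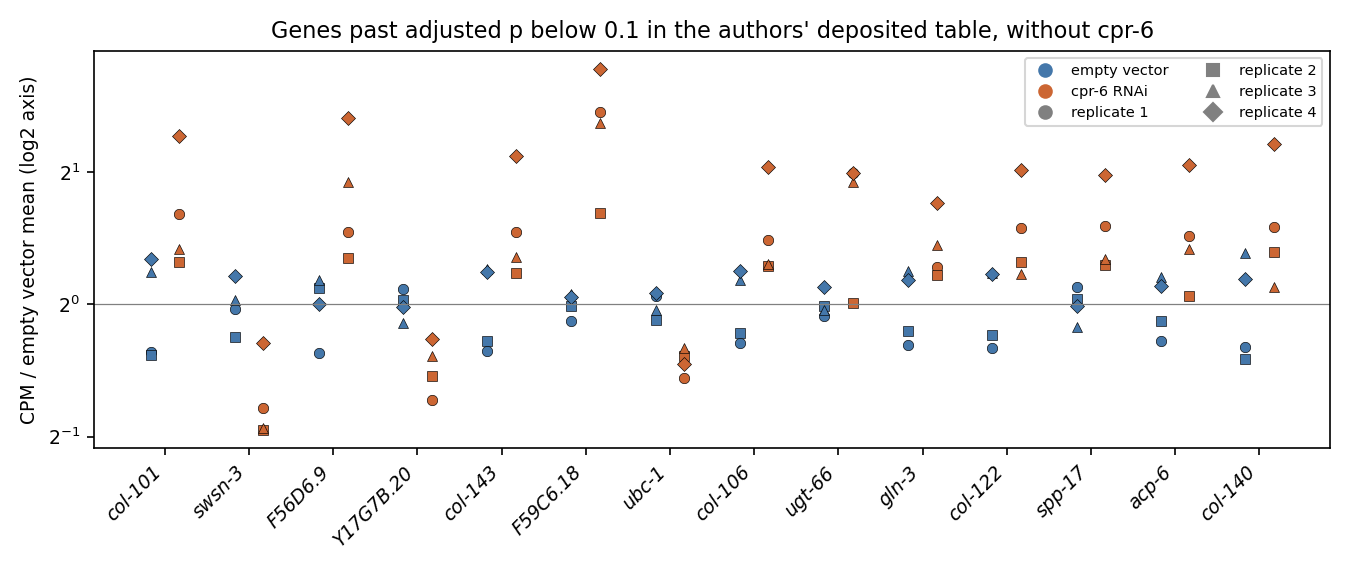
CPM of each library divided by the empty vector mean of the gene (log2 axis), for the 14 genes besides cpr-6 at adjusted p under 0.1 in the authors' deposited table. Points are libraries, coloured by group and shaped by replicate number. cpr-6 RNAi replicate 4 is the highest for the 5 collagens and for F56D6.9, F59C6.18, gln-3, spp-17 and acp-6.

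No other cathepsin B family gene passed the test, and levels of the abundant members lay close together in both groups. cpr-4 stood at 654 ± 28.5 CPM in empty vector and 658 ± 95.4 CPM in cpr-6 RNAi libraries (SD, n = 4), cpr-5 at 1080 ± 254 and 1106 ± 213 CPM, and cpr-1 at 658 ± 40.0 and 596 ± 109 CPM. Log2 fold changes were 0.01 for cpr-4 (95% interval -0.19 to 0.21), 0.03 for cpr-5, -0.14 for cpr-1 (-0.38 to 0.10), 0.26 for cpr-3, 0.01 for cpr-8, 0.01 for F57F5.1, -0.07 for F32H5.1, -0.01 for Y65B4A.2 and -0.76 for the scarce W07B8.4. Of the 9 measured members, 0 passed edgeR's test over all genes, 0 when adjusted over the list alone and 0 at unadjusted p under 0.05. The camera call for the list was not significant (adjusted p = 0.611; adjusted p = 0.847 with an estimated correlation). The list's mean log2 fold change was -0.07 with all libraries. Without cpr-6 RNAi replicate 4 it was -0.18 (camera adjusted p = 0.0507, and 0.0496 with the genes of all libraries kept), and no list was called there with an estimated correlation. With the genes of all libraries kept, it was 0.04 without cpr-6 RNAi replicate 1 (camera adjusted p = 0.434) and -0.02 without empty vector replicate 3 (0.957).

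The series title speaks of mechanisms that regulate ageing, and insulin/IGF signalling is the best known of them in worms. Of its 23 measured components, 0 passed edgeR's test over all genes, 0 when adjusted over the list alone and 0 at unadjusted p under 0.05. The FOXO transcription factor gene daf-16 had a log2 fold change of -0.10 (95% interval -0.30 to 0.09), hsf-1 -0.04 (-0.26 to 0.18), skn-1 -0.01 (-0.19 to 0.17), age-1 -0.24, smk-1 -0.20, akt-2 0.41 and the scarce receptor gene daf-2 -0.27. Camera called the list lower (mean log2 fold change -0.04, 17 of 23 members below 0, adjusted p = 0.0466; adjusted p = 0.745 with an estimated correlation). The call was lost without empty vector replicate 1 (-0.05), 2 (-0.03) or 3 (-0.03) and without cpr-6 RNAi replicate 4 (-0.02), and under the strict low-count filter, with about the same mean (-0.04, adjusted p = 0.0532). With no low-count filter the list was called with a mean of -0.14. Targets of daf-16 were not called. The DAF-16 induced list had an adjusted p of 0.550 in camera, with 3 members higher and 1 lower at unadjusted p under 0.05, and the DAF-16 repressed list one of 0.299. Insulin-like peptides had 0.0674. Of the genes tied to the transgene of CL2006, the marker gene rol-6 stood at 561 ± 91.0 and 637 ± 34.3 CPM (SD, n = 4), and unc-54, whose promoter drives the peptide, at 2879 ± 894 and 3574 ± 506 CPM. Their log2 fold changes of 0.18 and 0.31 did not pass edgeR's test.

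Among the 34 lists, camera with the preset correlation called 12 higher and 4 lower under cpr-6 RNAi. With an estimated correlation 0 were called (smallest adjusted p = 0.552; 2 lists at unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.306; 3 lists at unadjusted p under 0.05). Of the 16 called lists, body wall muscle and phase I and II detoxification kept their camera call whichever of the 8 libraries was left out. Leaving out empty vector replicate 1, 2 or 3 lowered the camera count to 9, 6 or 10, and leaving out cpr-6 RNAi replicate 4 lowered it to 9. These fits applied the low-count filter anew. With the genes of all 8 libraries kept, chosen after seeing the data, these counts were 12, 8, 11 and 10. No list had a member past edgeR's test over all genes. Adjusted over the list alone, 1 gene passed among innate immunity effectors (spp-17), 1 among the other lysosomal proteases (the aspartyl protease gene asp-4, 314 ± 22.6 and 395 ± 41.3 CPM, log2 fold change 0.33), and 0 in each of the other lists.

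Body wall muscle genes had the strongest camera call, with 24 of 26 members above 0 and a mean log2 fold change of 0.19 (adjusted p = 2.22e-07; adjusted p = 0.745 with an estimated correlation). The actin gene act-4 stood at 548 ± 48.5 and 634 ± 8.22 CPM (SD, n = 4). The tropomyosin gene lev-11, the myosin light chain gene mlc-2 and the troponin gene tnt-2 had log2 fold changes of 0.29, 0.26 and 0.25. Cuticle collagens followed, with 69 of 101 members above 0 and a mean log2 fold change of 0.20 (adjusted p = 1.65e-06; adjusted p = 0.745 with an estimated correlation). col-106, col-122, col-95 and col-42 had log2 fold changes of 0.56, 0.57, 0.54 and 0.58. List levels overlapped between the groups, with exact two-sided permutation p of 0.343 for muscle and 0.571 for collagens. Within replicates 1 and 2 the levels differed by 0.47 and 0.53, and within replicates 3 and 4 by -0.02 and -0.10. The muscle mean log2 fold change was 0.07 without empty vector replicate 1, 0.13 without empty vector replicate 2, 0.12 without cpr-6 RNAi replicate 4 and 0.30 without empty vector replicate 4. The collagen call was lost without empty vector replicate 1 (0.05) and without cpr-6 RNAi replicate 4, where the mean log2 fold change was -0.06, the difference of levels was -0.00331 and camera's direction stayed up. The collagen mean was 0.12 without empty vector replicate 2, 0.37 without empty vector replicate 3 and 0.36 without cpr-6 RNAi replicate 3.

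Phase I and II detoxification genes were called higher, with 86 of 114 members above 0 and a mean log2 fold change of 0.17 (adjusted p = 3.96e-06; adjusted p = 0.552 with an estimated correlation). Without cpr-6 RNAi replicate 4 the mean was 0.06 (adjusted p = 0.0381), and the level of the list in that library lay 0.33 above the mean of the 8 libraries. Its leading members were ugt-66 and the cytochrome P450 genes cyp-35D1, cyp-33A1 and cyp-43A1, with log2 fold changes of 0.78, 0.85, 0.75 and 0.53. The SKN-1 and oxidative stress list was called higher by 0.11 (adjusted p = 0.0466; adjusted p = 0.552 with an estimated correlation), led by nit-1, alh-5, gst-13 and gst-4 at 0.53, 0.42, 0.37 and 0.27. This call was kept in 1 of 8 fits with a library left out, where the filter let in 2 or 3 more genes, and in 4 of 8 fits over the same 22 genes. Over the same genes the mean was lowest without cpr-6 RNAi replicate 4 (0.06) and without empty vector replicate 3 (0.09), and the levels differed by 0.07 and 0.08 there. The call was also lost with RLE scaling (mean 0.10, adjusted p = 0.0535), with the strict low-count filter (0.10, 0.0562) and with no low-count filter (0.06, 0.154). Hypoxia response genes were called higher (adjusted p = 0.0139; adjusted p = 0.552 with an estimated correlation), as were innate immunity effectors (adjusted p = 0.0178; adjusted p = 0.745 with an estimated correlation), where spp-17, spp-9 and spp-23 had values of 0.58, 1.02 and 0.49 and irg-4 one of -0.52. The hypoxia call was lost without empty vector replicate 2 (mean 0.19, but kept at adjusted p = 0.0483 over the same genes) and without cpr-6 RNAi replicate 4 (0.13), and the innate immunity call without empty vector replicate 2 (0.08), empty vector replicate 3 (0.10) and cpr-6 RNAi replicate 4 (-0.01).

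Autophagy genes and lysosomal lipases were called lower. In the autophagy list 20 of 26 members lay below 0, with a mean log2 fold change of -0.09 (adjusted p = 0.0153; adjusted p = 0.552 with an estimated correlation). The phosphatidylinositol kinase gene vps-34 stood at 14.3 ± 0.810 and 10.2 ± 1.99 CPM (SD, n = 4), a log2 fold change of -0.49, with atg-10, atg-9 and epg-4 at -0.37, -0.41 and -0.20. All 5 measured lysosomal lipases lay below 0, with a mean log2 fold change of -0.28 (adjusted p = 0.0153; adjusted p = 0.552 with an estimated correlation), and lipl-1, lipl-3, lipl-2 and lipl-5 at -0.43, -0.58, -0.14 and -0.12. The lipase call was lost without cpr-6 RNAi replicate 1 (mean -0.18), and the autophagy call also (-0.07). The lipase call was lost without cpr-6 RNAi replicate 2 (-0.14) or empty vector replicate 1 (-0.18) too, where the filter let in 1 more lipase. With the same 5 lipases it was kept in both fits (-0.28 and -0.28), and the levels differed by -0.29 and -0.28, as against -0.28 with all libraries. The exact two-sided permutation p was 0.0286 for autophagy, nuclear-encoded oxidative phosphorylation and the SKN-1 list, where the groups did not overlap, and 0.0571 for the lipases. The smallest adjusted p of the 34 exact tests was 0.324, but no list could pass after adjustment unless 20 lists shared the smallest p that 4 against 4 allows. Lists of the lysosome membrane and v-ATPase (camera adjusted p = 0.158) and other lysosomal proteases (0.701) were not called. The latter had a mean log2 fold change of 0.01, but without cpr-6 RNAi replicate 4 camera called them lower (-0.07, adjusted p = 0.0285). With an estimated correlation 0 lists were called in that fit. Without cpr-6 RNAi replicate 2 or 3 the mean was 0.04 in each, with no call (camera adjusted p = 0.596 and 0.718).

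Nuclear-encoded oxidative phosphorylation genes were called higher by 0.06, with 42 of 50 members above 0 (adjusted p = 0.0153; adjusted p = 0.552 with an estimated correlation), and cytosolic ribosomal proteins by 0.05, with 66 of 79 above 0 (adjusted p = 0.0152; adjusted p = 0.745 with an estimated correlation). The mitochondrial genome list (adjusted p = 0.0153; adjusted p = 0.745 with an estimated correlation) was called higher by 0.31, and its level was high in cpr-6 RNAi replicate 4 alone among the cpr-6 RNAi libraries. Vitellogenins (adjusted p = 0.0153), neuron genes (0.0178) and pharynx genes (0.0466) were called higher and oocyte and eggshell genes (0.0178) lower, each with an adjusted p = 0.745 with an estimated correlation. Without cpr-6 RNAi replicate 4 the mean log2 fold change was -0.13 for the mitochondrial genome and 0.04 for oocyte and eggshell genes, both called by camera in the other direction. Neuron (-0.01) and pharynx (-0.06) means were below 0 there without a call, while camera's direction stayed up and their levels differed by 0.02 and 0.05. The vitellogenin call was lost without cpr-6 RNAi replicate 1 (mean 0.10 in place of 0.26), empty vector replicate 1 (0.17) or empty vector replicate 2 (0.21). Without empty vector replicate 1 or 2 the neuron (0.04 and 0.03) and pharynx (0.01 and 0.03) calls were lost, and without empty vector replicate 2 or 3 the oocyte (-0.04 and -0.05) and oxidative phosphorylation (0.05 and 0.06) calls. The oxidative phosphorylation call was also lost without cpr-6 RNAi replicate 2 (0.05), and the mitochondrial genome call without empty vector replicate 3 (0.26). The ribosomal protein call was kept in 3 of 8 fits (5 with the genes of all libraries kept), and was lost without empty vector replicate 2 (0.04) or 3 (0.02) and without cpr-6 RNAi replicate 1 (0.04), 2 (0.05) or 4 (0.03). With no low-count filter the calls of ribosomal proteins (mean 0.05, adjusted p = 0.0808), oxidative phosphorylation (0.01, 0.103), neuron genes (0.01, 0.0719), pharynx genes (-0.00116, 0.0733) and innate immunity effectors (0.02, 0.0946) were lost. Camera did not call cytosolic heat shock (adjusted p = 0.513), the ER (0.607) and mitochondrial (0.459) unfolded protein responses, the proteasome (0.158), C-type lectins (0.182), the intracellular pathogen response (0.696), lipid metabolism (0.116), intestine (0.130), germline cell division (0.0591), sperm (0.0674), embryonic transcripts (0.714) or the small RNA pathway (0.0585). Germline cell division and the small RNA pathway were called lower, each without empty vector replicate 4 (-0.07 and -0.06) and without cpr-6 RNAi replicate 1 (-0.07 and -0.09), 2 (-0.08 and -0.06) or 3 (-0.06 and -0.06), while without cpr-6 RNAi replicate 4 their means were 0.04 and 0.01 with no call. Sperm genes were called higher without empty vector replicate 3 (0.37) or 4 (0.21) or cpr-6 RNAi replicate 3 (0.29). Insulin-like peptides were called higher without cpr-6 RNAi replicate 1 (0.22), and intestine genes without cpr-6 RNAi replicate 3 (0.12). Without cpr-6 RNAi replicate 2 the proteasome was called lower (-0.05) and C-type lectins (0.14) and lipid metabolism (0.09) higher. With the genes of all libraries kept, insulin-like peptides were also called higher without empty vector replicate 3 (0.23) or 4 (0.14), and the small RNA pathway lower without empty vector replicate 1 (-0.06). In each of these fits with a library left out, camera with an estimated correlation called 0 lists. With a term separating replicates 1 and 2 from 3 and 4, chosen after seeing the data, camera also called insulin-like peptides higher (adjusted p = 0.0371), and germline cell division (0.0429) and the small RNA pathway (0.0472) lower. With that term and an estimated correlation it called 0 lists.

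**Figure D3:**
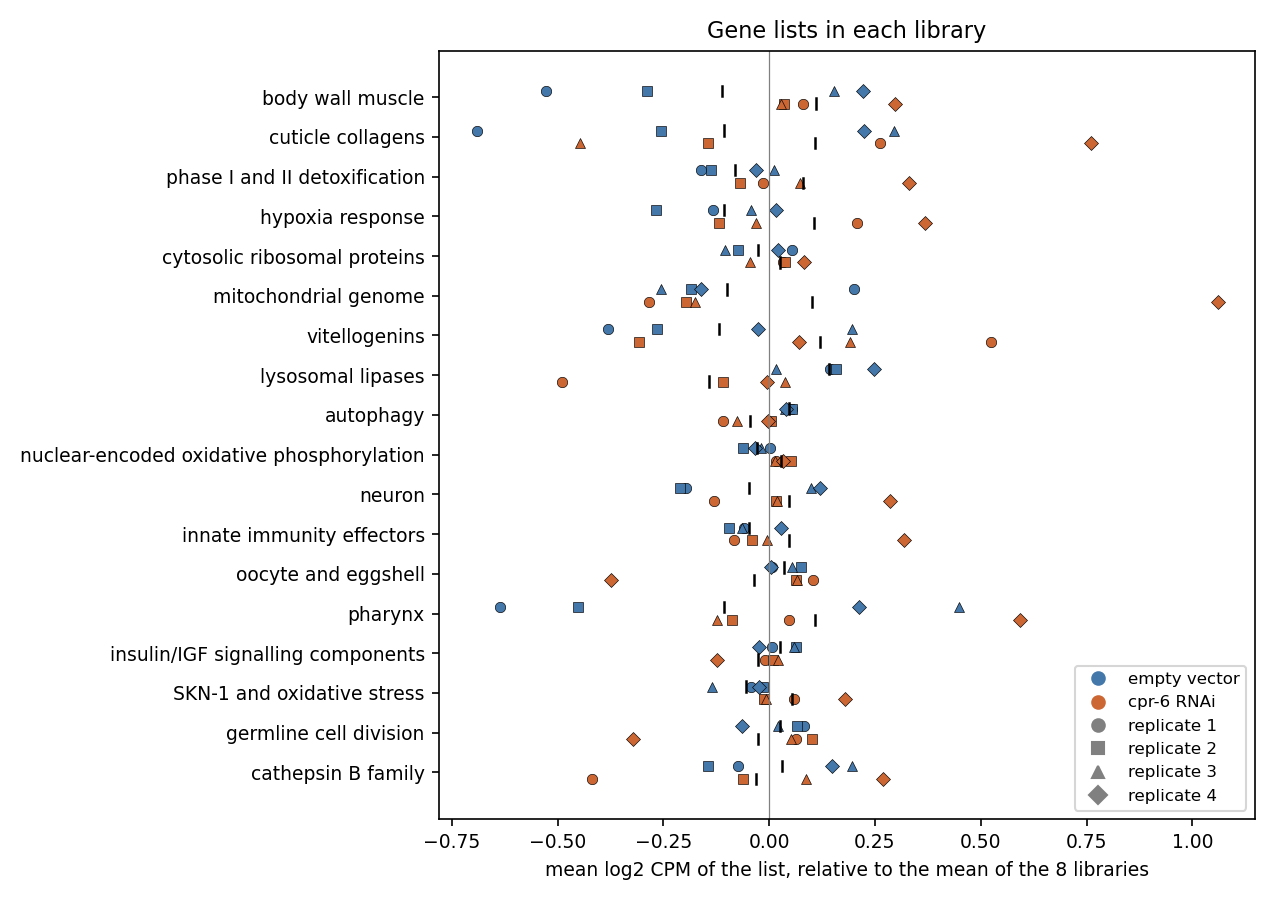
Mean log2 CPM of each gene list relative to the mean of the 8 libraries, for the 16 lists called by camera with the preset correlation and for germline cell division and the cathepsin B family. Points are libraries, coloured by group and shaped by replicate number, and vertical marks are group means (n = 4); cpr-6 RNAi replicate 4 reaches 1.06 for the mitochondrial genome.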

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

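The tests of a batch shared with empty vector replicate 4 and of the germline share were chosen after the result was seen. Within groups of 4 libraries, 100 sets of values were searched for a library far from the others, and 8 were found where chance gives 5, about 1 set in 20. The sets are not independent, since the mitochondrial share and the mitochondrial genome list rest on largely the same genes. The 8 are therefore not 8 separate findings. Of the 8, 6 were in cpr-6 RNAi replicate 4. There the mitochondrial genome took 2.144% of counts and its list stood at 1.06 on the log2 scale (-0.28 to -0.18 in the other 3 cpr-6 RNAi libraries). The oocyte and eggshell list stood at -0.37, germline cell division at -0.32 and embryonic transcripts at 0.31 in that library, and K06A5.1 at 38.8 CPM against 41.5 to 41.9. The other 2 were the proteasome list in empty vector replicate 1 at 0.0888 and ugt-66 in cpr-6 RNAi replicate 2 at 14.1 CPM, against 26.7 or more in the other cpr-6 RNAi libraries.

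The distance of cpr-6 RNAi replicate 4 from the other libraries was weighed; the design names no difference that sets 1 library of a group apart. A rise of mitochondrial RNA of both genomes is argued against, because the excess of nuclear-encoded oxidative phosphorylation genes was 0.348% of that of the mitochondrial genome. A batch shared with empty vector replicate 4 is argued against as the source of the mitochondrial excess, since that library ranked 3 of 4 among the empty vector libraries in mitochondrial share, although the pair's deviations correlated at 0.249 across genes. A lower share of germline RNA may contribute, but as the whole cause it would raise somatic lists alike. The excess of cuticle collagens was 0.62 above that of body wall muscle (SE over genes 0.0740). Genes of a list vary together (estimated correlation 0.515 for collagens and 0.753 for muscle), so this SE is too small. Collagen levels also ran from -0.45 to 0.26 in the other cpr-6 RNAi libraries. The test therefore cannot decide on germline RNA as the whole cause. cpr-6 RNAi replicate 4 also held the largest share of rRNA genes (0.227% of counts, against 0.0605% to 0.157% in the other 7). Differences in worm stage, RNA quality or library preparation stay open as untested.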

How the results depend on the processing

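The term separating replicates 1 and 2 from 3 and 4, the exact permutation of list means and the leave-outs over the genes of all libraries were chosen after seeing the data. The cpr-6 fall passed under all 18 alternatives, with log2 fold changes from -3.34 to -3.13. The count of 1 gene became 28 with no low-count filter (18 higher, 10 lower), 5 with DESeq2 and 7 with DESeq2, that term and a minimum of 24 summed counts in place of its own filter, and ran from 1 to 3 with a library left out. The 3 came without cpr-6 RNAi replicate 4 (cpr-6, swsn-3, Y17G7B.20), and 2 came without cpr-6 RNAi replicate 2 (cpr-6, ugt-66). With the replicate number as a replicate block 2 genes were called (cpr-6, C30E1.9). That block and the term separating replicates 1 and 2 from 3 and 4 each gave 19 lists, the 16 with insulin-like peptides, germline cell division and the small RNA pathway. Each gave 0 lists with an estimated correlation. Whether same-numbered libraries pair could not be decided from 4 correlations. Their deviations correlated over 0.1 for 2 of 4 numbers (-0.03 to 0.25), and 1 of 4 cpr-6 RNAi libraries correlated best with its own number. In edgeR, 570 genes had unadjusted p under 0.05 with the replicate block. With the term separating replicates 1 and 2 from 3 and 4 it was 547, and with treatment alone 421. Between the groups, deviations correlated at 0.0686 on average within replicates 1 and 2 or within 3 and 4, and at -0.0699 across them. A source shared along that division therefore stays open. The 10 genes given as values kept their direction under every alternative, on the same side of the threshold in 163 fits and past it in 17. Their choice by smallest p in these same libraries made a turn of direction unlikely. The count of 16 lists became 0 with an estimated correlation, 0 by fry and 0 by exact permutation, where none could pass unless 20 lists shared the smallest p, and ran from 6 to 20 with a library left out (6 without empty vector replicate 2, 9 without empty vector replicate 1 and without cpr-6 RNAi replicate 4, 10 without empty vector replicate 3). Over the genes of all libraries it ran from 8 to 20 (8, 12, 10 and 11 in the same order), since the filter applied anew let in low-count genes. RLE factors gave 15 (SKN-1 list lost) and the strict low-count filter 14 (SKN-1 list and insulin/IGF lost). No low-count filter gave 15, with 10 of the 16 among them. It lost ribosomal proteins, oxidative phosphorylation, innate immunity, pharynx, neuron and the SKN-1 list, and gained insulin-like peptides, proteasome, germline cell division, sperm and the small RNA pathway. With a library left out, mean log2 fold changes ran from -0.133 to 0.438 for the mitochondrial genome, -0.00960 to 0.136 for innate immunity effectors, -0.0636 to 0.374 for cuticle collagens, -0.104 to 0.0386 for oocyte and eggshell, -0.0577 to 0.361 for pharynx and -0.00819 to 0.138 for neuron genes, each mean with its sign turned without cpr-6 RNAi replicate 4. Over the genes of all libraries these means without that replicate were -0.134, -0.0117, -0.0594, 0.0378, -0.0586 and -0.00903. Camera's direction turned for 3 of these 6 lists (mitochondrial genome, innate immunity, oocyte) and stayed up for collagens, pharynx and neuron. Levels still differed by 0.00465 for innate immunity, 0.0526 for pharynx and 0.0159 for neuron genes. With no low-count filter the pharynx call was lost (adjusted p = 0.0733), with a mean of -0.00116 and camera's direction up. The cause was not tested. Depth limits the least abundant of 4 equal classes of genes (median count 19.4), where 60.6% of the 95% intervals lay within 2-fold.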

Other observations

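The tests of GO terms, with all libraries and with 1 left out, of an estimated correlation as an explanation, of low values in empty vector replicates 1 and 2 and of each list without cpr-6 RNAi replicate 4 were chosen after the results were seen. Across 944 GO terms of 10 to 500 measured genes, cpr-6 left out, camera with the preset correlation called 22 higher and 85 lower. Structural constituents of the cuticle had a mean log2 fold change of 0.20, neuropeptide signalling 0.14 and glutathione metabolism 0.17, against -0.07 for DNA repair, -0.08 for DNA replication and -0.07 for the meiotic cell cycle. With an estimated correlation 0 terms were called (smallest adjusted p = 0.796). Without cpr-6 RNAi replicate 4 also 0 terms were called (smallest adjusted p = 0.273), with means of -0.07 for the cuticle, 0.03 for neuropeptide signalling, 0.03 for glutathione metabolism, -0.03 for DNA repair, -0.02 for DNA replication and -0.01 for the meiotic cell cycle. Without empty vector replicate 2 the count was 19, and without any other library it ran from 63 to 188. As many terms as the real 107 were called in 16 of the 35 splits of the libraries into 4 and 4, with 233 as the highest of the others, so chance is not excluded.

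The counts of calls were set against other splits of the same libraries. As many genes as the real 1 were called in 4 of the 35 splits, with 5 as the highest of the others, although only the grouping by treatment separates cpr-6. The split with 5 set replicates 1 and 2 of both groups against the other replicates. The deposited values match a model with a term for that division, so a source shared along it may raise this count. The split is therefore not a plain chance regrouping. That split also gave 16 lists. As many lists as the real 16 were called in 9 of the 35 splits, with 17 as the highest of the others, so chance is not excluded for the list count either. Genes of a list that vary together between libraries may account for it, and 0 of the 16 lists kept adjusted p under 0.05 with an estimated correlation. That loss cannot decide the question, since none of the 35 splits gave a list called with an estimated correlation. The estimate was 0.753 for body wall muscle, but near the preset 0.01 for the SKN-1 list (0.0161) and autophagy (0.0200), which were lost too. Camera's unadjusted p still rose from 0.0219 to 0.0722 for the SKN-1 list and from 0.00447 to 0.0409 for autophagy. A loss of calls with an estimated correlation therefore does not show that correlation between genes alone removed them. A single library could also set much of the count, which dropped to 6 without empty vector replicate 2.

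Body wall muscle and cuticle collagen lists were higher under cpr-6 RNAi on average. Within replicates 3 and 4 the larger of both differences was -0.0242, as low values in empty vector replicates 1 and 2 would give. High values in empty vector replicates 3 and 4 would give this too, so the test cannot tell them apart. Muscle levels there were 0.15 and 0.22, against 0.08, 0.04 and 0.03 in cpr-6 RNAi replicates 1 to 3. For collagens cpr-6 RNAi replicate 3 (-0.45) lay below empty vector replicate 2 (-0.26). Whether cpr-6 RNAi replicate 4 alone carries the difference of both lists cannot be told apart, since without it the collagens kept -31.1% of their mean log2 fold change of 0.20 and muscle kept 61.2% of 0.19 (on list levels, -1.54% and 71.7%). Taken one by one, which was decided after that combined result was seen, the collagen mean log2 fold change went to -0.0636, as this explanation needs, and the muscle one to 0.12 (SE of the levels between libraries 0.180), which is too uncertain to decide. An effect of cpr-6 RNAi stays open, with exact permutation p of 0.343 for muscle and 0.571 for collagens.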
